A study of Mus musculus with 2 samples.

How the data were processed

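CTCF ChIP-seq peak lists of 2 libraries from the mouse embryonic stem cell line E14TG2a.4 were analysed. Per the labels, the libraries are biological replicates 1 and 2 of a single group, from a male line. The design has no second condition, so replicates were compared with each other and regions of the genome with one another.

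Per the deposited descriptions of the files, the mm10 lists hold peaks and background made as input for IDR, for each replicate and for both pooled, from filtered alignments with a control. Each of these 3 lists has 300000 entries with a signal per peak from the authors' peak caller, whose scale is not stated. A deposited −log10 q value stands beside it, and its highest value is shared by many peaks, 28984 in replicate 1. The authors' conservative and optimal IDR sets hold 43393 and 44306 peaks, with the signal and −log10 values of the pooled list and an integer score from 537 to 1000, deposited without an IDR version or threshold. The mm9 lists are deposited broad-peak calls for each replicate and for both together, with a fold enrichment per peak, a ratio on the authors' scale never below 2.81, and a −log10 p never below 5. Peak caller and aligner are not given in the sources used here. The deposited false discovery values of the mm9 lists were not used, since their scale is not stated. The lists give no read counts, so the depth is unknown and no floor was computed.

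Work on mm10 used the conservative set on the autosomes and X. A peak was shared when summits lay within 100 bp, and the background was the same list shifted by 10000 bp. IDR was recomputed with a copula mixture model on 55004 matched pairs ranked by signal, with a convergence tolerance of 1e-05, reached in 2687 of at most 8000 iterations. Relative signal was the signal divided by the replicate's median over the matched conservative peaks. Gene positions on mm10 came from a RefSeq table of assembly GRCm38.p6. Loci with 50 kb flanks were tested against 10000 random windows of the same length on the same chromosome.

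Genome sequence and gene models with transcription starts were used for mm9 only (GENCODE vM1), so annotation, motif, B2-related, orientation and gene list results used the mm9 pooled list, with the peak midpoint in place of the summit. This departs from the design fixed before the data were examined, which named the conservative set. No coordinates were converted or compared across builds. The sequence carried no repeat masking, so the planned share of summits in repeats was not computed.

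A 19 bp CTCF motif was refined by expectation maximisation from the textbook sequence TGGCCACCAGGGGGCGCTA on the 5000 strongest peaks of odd-numbered chromosomes, with 100 bp either side of the midpoint. It was evaluated on even-numbered chromosomes and X within 50 bp of the midpoint, at the score that 1% of flanking windows reach (14.9 bits). Flanking windows lay 500 to 5000 bp beyond the peak edge. The genome-wide scan used 12.9 bits, the 1% score with flanking windows inside other peaks left out, and the shares of motif sites inside peaks per chromosome used the 14.9 bits. B2-related peaks were those with a motif and the sequence within 150 bp with up to 3 mismatches. Promoters were 1000 bp either side of a transcription start of a protein-coding gene, and genes with a shared name were counted once.

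Random positions (1000 sets) kept chromosomes and left out assembly gaps. Correlations across peaks and chromosomes used 100000 resamples, or 2000 for alternatives. Gene lists (17) were tested by Fisher's exact test against all other protein-coding genes, and loci (30) by permutation, each with Benjamini-Hochberg adjustment over its family at 0.05. Tests were two-sided, and for X the distance of each chromosome's median from the median of the autosomes was ranked over 20 chromosomes. Intervals are exact Clopper-Pearson at 95%.

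Named in the text, by a rule fixed before the data were examined, are the 10 peaks of highest signal with their nearest gene, the strongest peak of fixed loci, up to 4 members per gene list with the strongest promoter peak by pooled fold enrichment and up to 2 without, and the 3 peaks per replicate with the largest rank difference. Not all items the rule takes are printed, and some are withheld for evaluation. Of the loci, those of general interest were printed and the rest summarised.

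Alternatives covered the shared-peak rule, number of peaks, IDR threshold, promoter and motif windows, motif threshold, flanks, background, peak set and leaving out each replicate, which meant using the other replicate's list alone. The optimal set and the pooled mm10 list were not run for results moved to mm9. The IDR model, the motif model, the position permutation and the gene list test were tested on simulated data, and the other steps were not. The IDR model, with 60.0% of 30000 simulated pairs reproducible, fitted 59.8%, and 4.89% of its calls were irreproducible. The motif model, with the motif planted in 68.1% of 2000 windows, fitted 69.4% and recovered 92.5% of planted motifs. The Fisher test passed for 98.7% of simulated lists with 4-fold odds and for 2% of unchanged lists, without adjustment. The position permutation passed for 2.5% of unchanged sets. Simulated lists had a single size and independent genes, and simulated sets drew counts without placing positions. These rates therefore do not carry over to lists of other sizes or of clustered genes. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.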

Results

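Binding of CTCF, the zinc-finger protein that marks insulators and anchors chromatin loops, was measured by ChIP-seq in E14TG2a.4, a male mouse embryonic stem cell line of 129/Ola origin. The series held 2 libraries, which are biological replicates 1 and 2 of a single group, so the comparisons were between the replicates and between regions of the genome. The measurements analysed were peak lists on the mm10 build, with a signal per peak, and peak lists on the mm9 build, with a fold enrichment per peak. The lists gave no read counts, so the depth of each library was unknown. Peaks are not independent replicates, 2 libraries allow no test between groups, and the confidence intervals cover counting error only.

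The strongest CTCF peak of the conservative set lay on chromosome 17 (mm10, 56763381 to 56763715), between genes and 1206 bp from Dus3l. Its pooled signal was 559.7, and it ranked 1 in each replicate. Relative to each replicate's median over the conservative set, its signal was 7.13 ± 0.0874 (SD, n = 2). The next strongest peaks lay inside Gm50595 on chromosome 2 (75605732 to 75606039; pooled signal 497.3, relative signal 6.35 ± 0.562) and inside Ndst1 on chromosome 18 (60706032 to 60706336; 464.6 and 5.92 ± 0.120), a gene of heparan sulfate synthesis. The others of the strongest 10 lay inside Nans, Niban2 and Tjp3, or between genes with Nmur2, Bcl7a, 1600014C23Rik and Glrx5 as the nearest protein-coding genes, with pooled signals of 394.8 to 462.1.

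Most strong CTCF sites were found in both replicates at similar strength. Of the 43344 strongest peaks of each replicate, as many as the conservative set holds on the autosomes and X, 85.8% (exact 95% interval 85.4 to 86.1) had a summit within 100 bp among those of the other replicate. After a shift of 10000 bp, 0.715% and 0.789% did. Against the other replicate's full list, 99.95% of the strongest 10000 peaks of replicate 1 were found, 83.4% of those ranked 30001 to 40000, and 33.3% of those ranked 40001 to 50000. Signals of the 37177 peaks shared by the top lists had a Spearman's rho of 0.891 and, for log2 signal, a Pearson's r of 0.879 across peaks, and the log2 ratio between replicates had an SD of 0.42. Within the strongest 10000 peaks of the conservative set, chosen by pooled signal, rho was 0.565. The log2 ratio there had a smaller SD, 0.279, so the lower rho does not show poorer agreement in strength.

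**Figure D1:**
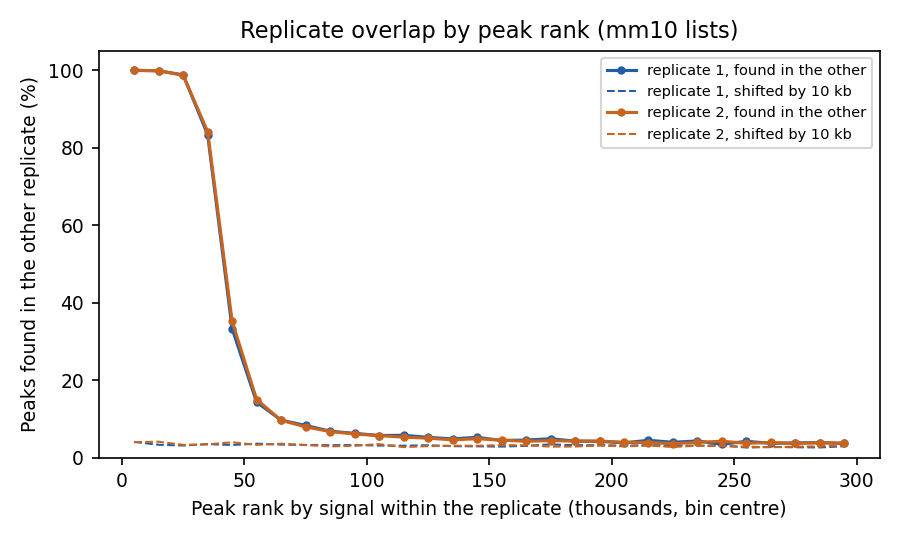
Share of peaks (%) found in the other replicate's full list against peak rank by signal (axis in units of 1000, centre of each bin of 10000 peaks), as solid lines for replicates 1 and 2 and as dashed lines after a shift of 10 kb. The share was 99.95% in replicate 1 for the strongest bin and 33.3% for ranks 40001 to 50000.

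Single peaks, matched to the nearest summit within 100 bp in each replicate, departed from this similarity in either direction. A peak inside Erc2 on chromosome 14 (27804202 to 27804332) had a relative signal of 1.89 in replicate 1 and 0.531 in replicate 2. Peaks near Lpo, which encodes lactoperoxidase, and inside Pih1d1 also ranked higher in replicate 1, with 1.505 against 0.494 and 1.66 against 0.580. The reverse held near Mtfmt on chromosome 9 (65434303 to 65434491), with 0.645 in replicate 1 and 2.46 in replicate 2, and for a peak near Hnrnpdl (0.415 and 1.51). These peaks were among the 3 largest rank differences per direction. At Erc2 the pooled signal, 67.7, was below that of replicate 1 alone, 77.2. Near Mtfmt the pooled signal, 92.5, was below that of replicate 2 alone, 93.4. A neighbouring summit can be taken by the match, and whether the same site was matched was not tested. Of the conservative peaks matched in both replicates, 82.6% differed by less than 1.5-fold and 3.18% by more than 2-fold, 638 of them higher in replicate 1 and 680 in replicate 2.

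The conservative and optimal sets differed in weak sites. On the autosomes and X the conservative set held 43344 peaks and the optimal set 44264. Of these, 93.7% of conservative peaks overlapped an optimal peak, and 91.6% of optimal peaks overlapped a conservative peak. The 2713 peaks found in the conservative set alone had a median signal of 20.7 and the 3700 found in the optimal set alone 20.6, against 77.2 for the whole conservative set. Recomputing the irreproducible discovery rate (IDR) from the replicates' lists gave 43143 peaks at a threshold of 0.05, of which 94.97% lay in the conservative set, and 94.5% of the conservative set was found.

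Among 30 loci fixed before the data were examined, the clustered protocadherin genes, which give neurons their surface identity, and Firre, an X-linked gene for a noncoding RNA, held more CTCF peaks than random windows of their chromosomes. The protocadherin window on chromosome 18 (mm10, 36880285 to 37891873) held 81 conservative peaks against a random mean of 14.4, a 5.63-fold excess. Its strongest peak (37751379 to 37751651, inside Gm37013) had a signal of 280.2 and a relative signal of 3.59 ± 0.0866 (SD, n = 2). The Firre window on X (50513120 to 50685321) held 14 peaks against 1.04, a 13.4-fold excess, with a strongest peak of relative signal 2.28 ± 0.0433. Two-sided permutation tests over 10000 random windows gave Benjamini-Hochberg adjusted p of 0.027 for the protocadherins and 0.024 for Firre. Against windows centred on protein-coding genes, an alternative added after the data were seen, the Firre ratio was 7.20 (permutation test, adjusted p = 0.006), and the protocadherin ratio was 2.82 with an adjusted p of 0.433. With flanks of 100 kb the protocadherin ratio was 5.24 with an adjusted p of 0.0760, and with 0 kb the Firre ratio was 20.5.

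The other 28 loci did not pass the test, and their values follow as description. Pou5f1, which encodes the pluripotency factor OCT4, had 12 peaks in its window against a random mean of 2.18 (adjusted p = 0.156, permutation test). Windows around the pluripotency genes Nanog, Sox2 and Prdm14 held 6 peaks each, and that of Esrrb held 8. The strongest of them were at 122669452 to 122669723 on chromosome 6 for Nanog (relative signal 3.42 ± 0.253) and at 35534462 to 35534693 on chromosome 17 for Pou5f1 (3.21 ± 0.247, inside Psors1c2), SD with n = 2. In the Shh window, which takes in the limb enhancer of this signalling gene, the strongest peak lay inside Lmbr1 on chromosome 5 (29293268 to 29293552), with a relative signal of 4.36 ± 0.246 and pooled rank 43. The window of Ctcf itself held 9 peaks, the strongest 93 bp from Carmil2 with 2.76 ± 0.236.

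The Hox clusters, which pattern the body axis, held 4 peaks between the ends of HoxA, 10 in HoxB, 4 in HoxC and 5 in HoxD, or 3.46 to 5.75 per 100 kb. The strongest HoxA peak lay 1263 bp from Hoxa9 (52221704 to 52221966 on chromosome 6; relative signal 2.94 ± 0.101), and the strongest HoxC peak lay 234 bp from Hoxc10 (102966502 to 102966652 on chromosome 15; 1.56 ± 0.0420). Imprinted windows ranged from 4 peaks at Peg3, Grb10 and Rasgrf1 to 20 at Kcnq1, where the strongest lay inside Trpm5 with 2.63 ± 0.343. The alpha-globin window held 9 peaks and the beta-globin window 2, or 1 with either replicate left out and in the optimal set. The strongest peak of the X-inactivation centre had a relative signal of 0.886 ± 0.000790, and that at Gnas 0.706 ± 0.434. No globin, Hox or imprinted window passed the permutation test.

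At the imprinted pair H19 and Igf2 the window held 6 conservative peaks, the strongest 35148 bp from Ins2 (142714766 to 142714964 on chromosome 7; relative signal 2.20 ± 0.0441). The 10 kb upstream of H19, where the imprinting control region with its textbook CTCF sites lies, held 0 peaks of the conservative or optimal set. The nearest conservative peak lay 32605 bp beyond the end of H19 (142610593 to 142610908) with a signal of 67.8. Replicates 1 and 2 each listed 3 entries in those 10 kb, with highest signals of 6.12 and 6.72, near the medians of the full lists, 6.74 and 6.08. A list of peaks above a threshold does not show that binding was absent.

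CTCF peaks on chromosome X were weaker and sparser than on every autosome. The median signal of conservative peaks was 49.6 on X and ranged from 73.2 to 82.1 on the 19 autosomes, a ratio of 0.627 to the autosomes' median. For the strongest peaks of each replicate's own list, as many as the conservative set holds, the ratio was 0.650 in replicate 1 and 0.632 in replicate 2. X held 6.13 peaks per Mb against an autosomal median of 17.7. It was also lowest in CTCF motif sites, with 31.6 per Mb against 50.2 in mm9, and in entries of the pooled list of peaks and background, with 20.03 per Mb against 124.6. In the mm9 lists, 11.4% of the CTCF motif sites on X lay inside a peak of replicate 1 and 10.8% inside one of replicate 2, against autosomal medians of 22.5% and 22.8%. An exact permutation over which of the 20 chromosomes is called X gave p = 0.05, the smallest it can give, so this test cannot pass a threshold below that value.

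**Figure D2:**
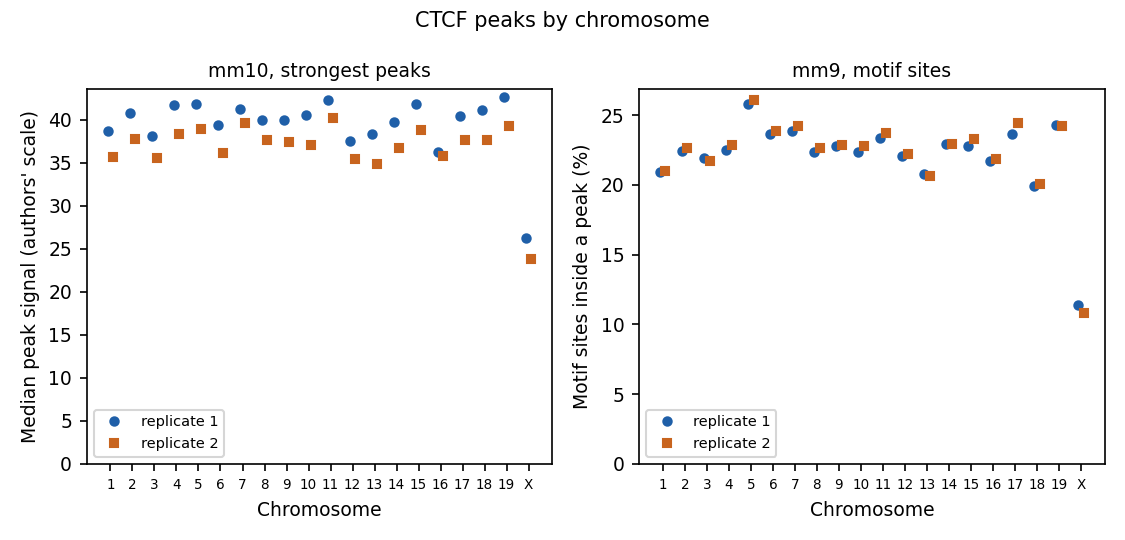
Median peak signal per chromosome on the authors' scale for the strongest peaks of each replicate (mm10, left) and share of CTCF motif sites inside a peak (%, mm9, right), with 1 point per replicate and chromosome. X lay below all autosomes in both panels, with 11.4% and 10.8% of motif sites inside a peak of replicates 1 and 2.

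Across the 19 autosomes, peak density followed gene density, with the highest peak density, 27.3 per Mb, on chromosome 11. Conservative peaks per Mb and protein-coding genes per Mb had a Pearson's r of 0.846 and a Spearman's rho of 0.875. Two-sided permutation tests gave p = 2e-05 for each, the smallest they can give. Without chromosomes 7 and 11, which lie farthest from the median gene density, r was 0.852. This was the only such relation computed across chromosomes.

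The mm9 lists, separate calls on another build, held 36353 peaks of replicate 1, 36733 of replicate 2 and 39349 of the pooled data on the autosomes and X, with median widths of 846, 866 and 913 bp. Of the replicates' peaks, 93.6% and 92.5% overlapped a peak of the other, against 5.55% after a shift, and their fold enrichments had a rho of 0.903 across peaks. Promoters, within 1000 bp of a transcription start of a protein-coding gene, held 5.87% of pooled peak midpoints against 2.45% of random positions, a 2.40-fold excess. The replicates alone gave 5.78% ± 0.0272 (SD, n = 2). Exons were also over-represented (4.10% against 2.63%), as were introns (40.2% against 35.6%), and intergenic sequence held fewer peaks than random positions (49.8% against 59.3%). Each p was 0.002 in two-sided permutation tests, the smallest that 1000 random sets can give.

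**Figure D3:**
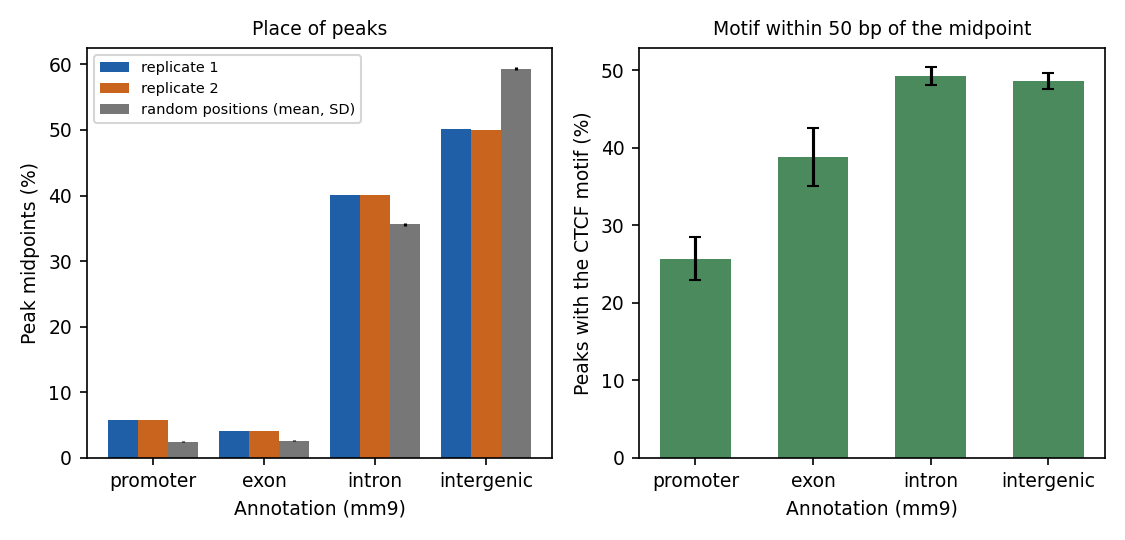
Left, share of mm9 peak midpoints (%) per annotation class for replicates 1 and 2, with random positions as mean and SD. Right, share of held-out pooled peaks with the CTCF motif within 50 bp of the midpoint (%, exact 95% intervals), which was 25.6% at promoters and 48.6% in intergenic sequence.

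The known CTCF recognition sequence was found at the centre of many peaks. A motif refined on odd-numbered chromosomes read TGGCCACCAGAGGGCGCTA at its most frequent bases and carried 17.2 bits. On the held-out chromosomes, 47.2% of 18233 pooled mm9 peaks (exact 95% interval 46.5 to 47.9) had it within 50 bp of the midpoint, against 0.784% of flanking windows. The peaks of replicates 1 and 2 gave 48.3% ± 2.67 (SD, n = 2). Promoter peaks carried it less often than intergenic peaks, 25.6% against 48.6% (Fisher's exact test, two-sided, p = 2.56e-45), with 38.8% in exons and 49.2% in introns. These shares depend on the score threshold and window, with 11.1% at a threshold that 0.1% of flanking windows reach and 65.9% at 5%. The best motif score within 50 bp of the midpoint was nearly unrelated to fold enrichment (rho = -0.0325, p = 2e-05, the smallest the permutation test can give). The sign was positive in each replicate's own list (0.0830 in replicate 1 and 0.0673 in replicate 2). With the best motif of the whole peak, added after the data were seen, rho was 0.130, and 0.123 and 0.0926 in replicates 1 and 2. Genome-wide, 7.59% of motif sites of 12.9 to 14 bits and 83.5% of those of at least 24 bits lay inside a pooled peak.

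CTCF motifs beside a sequence related to B2, a rodent short interspersed element known to carry CTCF motifs, were more frequent among weak than among strong peaks. Of 18256 motif-bearing pooled peaks, 18.2% (exact 95% interval 17.6 to 18.8) had the B2-related sequence TGGTTGTGAGCCACC with up to 3 mismatches within 150 bp, against 4.26% of positions 5 kb away, which were not chosen for a motif. With up to 2 mismatches the share was 12.3%, and with up to 4 it was 29.4%. Of all genome-wide motif sites of at least 12.9 bits, inside peaks or not, 41.3% had the flank. The share was 35.4% in the lowest quintile of peaks by fold enrichment and 8.27% in the highest quintile. Median fold enrichment was 8.44 for the 3320 peaks with the flank and 12.8 for the 14936 without it. Genome-wide, motif sites of 18 to 20 bits lay inside a peak in 6.45% of cases with the flank and 47.2% without, and sites of at least 24 bits in 79.4% and 86.1%. Whether reads can be placed in repeats as well as elsewhere was not tested. A lower share or fold enrichment with the flank therefore does not show weaker binding.

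Motif orientation, which is known to matter for chromatin loops, was compared with shuffled orientations for neighbouring peaks at several distances, and the distance classes were not tested against each other. Under 20 kb, a distance chosen after the data were seen and not run on either replicate alone, 20.1% of 4623 neighbouring motif pairs were convergent, 26.7% divergent and 53.2% tandem, against 25%, 25% and 50% after shuffling orientations within chromosomes (two-sided permutation p = 0.002 each, the smallest that 1000 shuffles can give). Neighbours 20 to 500 kb apart were convergent in 25.5% (permutation p = 0.0659), divergent in 24.3% (p = 0.016) and tandem in 50.2% (p = 0.695). Over all distances, convergent pairs made up 24.6% of 18236 pairs (permutation p = 0.018), and tandem pairs 50.9% against 50% (p = 0.02). Over all distances, the convergent share with the peaks of either replicate alone was 24.7% and 24.8%, with permutation p of 0.0779 and 0.218, and the tandem share was 50.6% and 50.5%, with permutation p of 0.0919 and 0.23.

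Among 17 gene lists fixed before the data were examined, promoters of clustered protocadherins and of ribosomal protein genes carried CTCF peaks more often than other genes, and those of olfactory receptors, vomeronasal receptors and keratins less often. In mm9, 10.3% of 22202 protein-coding genes had a pooled peak midpoint within 1000 bp of a transcription start. An entry with several starts counted once, with a peak at any of them. The share was 95.8% for clustered protocadherins (23 of the 24 entries listed), with Pcdhb1 as the exception. It was 27.3% for ribosomal protein genes (21 of 77), 1.01% for olfactory receptors (11 of 1087), 0 of 319 for vomeronasal receptors and 0 of 46 for keratins. Two-sided Fisher's exact tests with Benjamini-Hochberg adjustment gave 3.5e-21, 0.000101, 2.24e-36, 5.27e-15 and 0.0433 in that order. These tests take genes as independent, so for families whose members lie side by side the p-values overstate the evidence. The protocadherin window, tested as a single mm10 locus by permutation, had an adjusted p of 0.027, and of 0.433 against windows centred on protein-coding genes. Whether reads can be placed as well in families of similar genes was not tested. Random lists matched on promoter CpG ratio had shares of 4.45% for olfactory receptors and 3.10% for vomeronasal receptors, nearer to the observed ones than the share of all genes, and both lists still passed (permutation test, adjusted p = 0.00113 each). Keratins no longer passed with the peaks of either replicate alone (adjusted p 0.0680 without replicate 1 and 0.0562 without replicate 2) or with the strongest 10000 peaks (0.898).

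**Figure D4:**
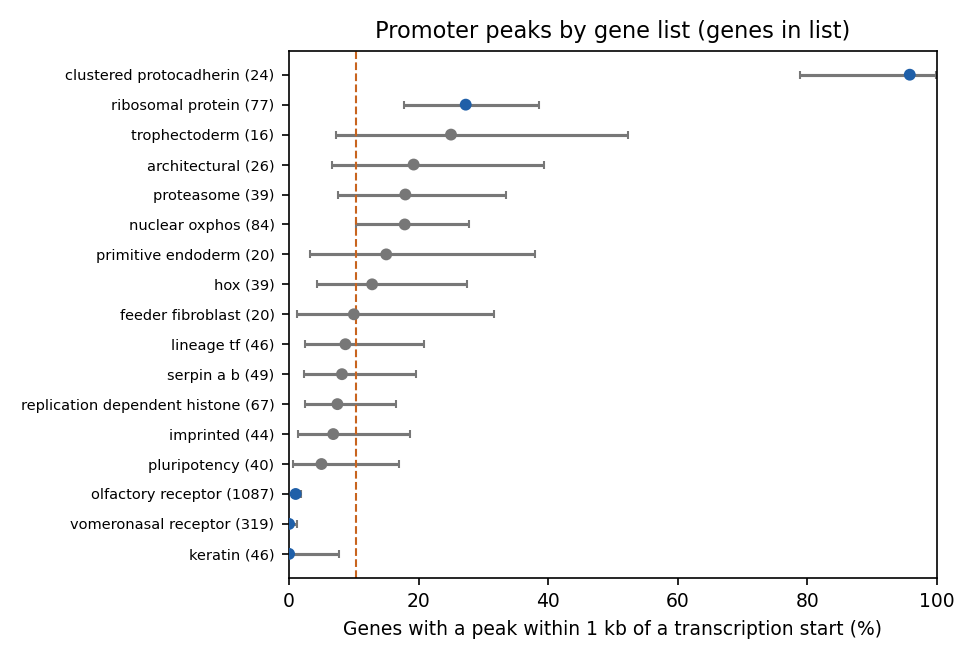
Share of genes (%) with a pooled mm9 peak within 1 kb of a transcription start for each of 17 gene lists, with list sizes in parentheses, exact 95% intervals and the share of all genes as a dashed line. Lists past the adjusted threshold are in blue, from clustered protocadherins at 95.8% to vomeronasal receptors and keratins at 0.

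Within the lists that passed, the strongest protocadherin promoter peak lay at the entry named Pcdhgc5 (mm9, chromosome 18, 37901129 to 37902138). Its fold enrichment was 28.7 ± 0.933 (mean of the replicates, SD, n = 2). Its midpoint lay in an intron, 114 bp from a start annotated to that entry, and whether the start is that of Pcdhgc5 itself was not tested. The next protocadherins were Pcdha11 with 25.2 ± 4.31, Pcdhb16 with 18.9 ± 1.67 and Pcdhb4 with 19.8 ± 0.0636. The midpoint at Pcdha11 also lay in an intron, 205 bp from a start annotated to that entry. Whether that start is that of Pcdha11 itself was not tested. Among ribosomal protein genes, Rpl26 on chromosome 11 (68714508 to 68715388) had 31.0 ± 4.64, Rps29 had 27.4 ± 0.417 and Rpl36 had 24.5 ± 2.14, while Fau and Rpl10 had no promoter peak. The few olfactory receptors with a peak included Olfr304 (13.1 ± 0.156), Olfr9 (11.97 ± 1.24), Olfr15 (11.1 ± 0.742) and Olfr763 (10.9 ± 2.74), and each of these midpoints lay in a coding exon.

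The other 12 lists did not pass. Pluripotency genes had promoter peaks at 2 of 40 members, Pou5f1 (chromosome 17, 35646026 to 35646847, in a coding exon; fold enrichment 7.66 ± 0.735) and Mycn (5.64 ± 0.509), and without replicate 1 the count was 4 of 40, on the other side of the background, which was then 9.51%. Lists of other cell types that such a culture could hold gave 3 of 20 for primitive endoderm, with Pdgfra at 14.2 ± 1.15, 4 of 16 for trophectoderm, with Elf5 at 24.8 ± 3.71 and Fgfr2 at 19.3 ± 3.39, and 2 of 20 for feeder fibroblasts, which were Col1a1 (18.4 ± 3.44) and Col1a2 (10.5 ± 0.969). Lineage transcription factors gave 4 of 46, or 2 of 46 without replicate 2, including Mesp1 at 20.2 ± 1.32 and Foxa1 at 13.3 ± 0.156. Hox genes gave 5 of 39, with Hoxa7 at 30.7 ± 1.01, where the peak midpoint lay 3 bp from the start, and Hoxc10 at 18.3 ± 2.38. Imprinted genes gave 3 of 44, which were Zim1 (20.6 ± 1.15), Asb4 (16.3 ± 4.14) and Gnas (6.99 ± 0.191). Genes of chromatin architecture gave 5 of 26, with the cohesin subunit gene Smc3 at 17.9 ± 2.93 and the cohesin loader gene Nipbl at 12.2 ± 0.290.

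Lists of housekeeping genes and of tandem gene families completed these 12. Nuclear genes of oxidative phosphorylation gave 15 of 84 (17.9%, Fisher's exact test, adjusted p = 0.0856), with Ndufv2 at 27.7 ± 4.06 and Ndufb10 at 26.0 ± 0.884, and passed with windows of 2500 bp (32.1%), of 5000 bp (50%) and without replicate 2 (20.2%). It did not pass against lists matched on CpG ratio, which had a share of 13.3% (permutation test, adjusted p = 0.548), or by Fisher's exact test with the strongest 10000 peaks (adjusted p = 0.181) and without replicate 1 (0.224). Proteasome genes gave 7 of 39, with Psmc6 at 33.8 ± 2.97 and Psmd6 at 21.2 ± 1.73. Replication-dependent histone genes gave 5 of 67, or 3 of 67 without replicate 1, with Hist1h4c at 23.0 ± 3.03, and serpins of clades A and B gave 4 of 49, with Serpinb9 at 13.3 ± 4.23. With windows of 5000 bp the Hox list passed as well, at 51.3%.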

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

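Tests of reads that cannot be placed upstream of H19, and the shares of sites without a B2-related flank there, were chosen after the result was seen. The other tests of this part were written before their results were seen.

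Peaks outside the autosomes and X were not part of any comparison. The conservative set held 17 peaks on the mitochondrial chromosome, with a median signal of 50.5 and a highest signal of 83.7, and each replicate listed 22 entries there. A further 32 conservative peaks lay on 7 sequences not placed on a chromosome, with a median signal of 26.4 and a highest signal of 304.8. No control library was used here, so these counts have no background.

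Median CTCF signal on X was 0.627 of the autosomes' median. Weaker motifs were argued against for X peaks with a motif, whose median score was 19.7 bits, the highest of the 20 chromosomes. That median covers called peaks only, and X peaks without a motif were left out. Among peaks with a motif, matched on motif score, X stayed lowest, at 0.746 of the autosomes' fold enrichment. The ratio was 0.755 for peaks with a motif before matching and 0.721 for all mm9 peaks. These ratios bear on motifs and do not decide for or against a single X copy. Whether every X peak was halved by copy number stayed open. The ratio of 90th percentiles, the test set beforehand with a bound of 0.6, was 0.602 in replicate 1 and 0.574 in replicate 2, mean 0.588. The ratios of medians of the same lists, 0.650 and 0.632, and of 99th percentiles, 0.648 and 0.651, lay above that bound, on a signal scale that is not stated. These lists are cut at the same signal for all chromosomes, so X peaks below the cut are left out. Ratios of the peaks that remain cannot count against a halving. With a single group, no explanation beyond copy number and motifs was tested.

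The 10 kb upstream of H19 held 0 thresholded peaks. That reads cannot be placed anywhere in these 10 kb was argued against, since each replicate's full list held 3 entries there. Those lists held 128.6 and 123.8 entries per Mb on chromosome 7, peaks and background together. Entries somewhere in the 10 kb do not show that reads can be placed in the control region, so for that region the test cannot decide. Whether weak CTCF motifs upstream of H19 explain the missing peaks was not decided. The 3 motif sites found in mm9 had 13.98 to 16.6 bits and lay 1126, 4854 and 9705 bp upstream. From the share of equally scored sites inside peaks, they would give 0.36 occupied sites, which met the rule set beforehand for this explanation. An average stretch of 10 kb would meet it too, since 2555.8 Mb held 195300 motif sites, of which 18.9% lay inside a pooled peak. None of the 3 sites upstream of H19 has a B2-related flank. From sites without that flank the sum was 0.491, with a chance of 0.576 that 0 are occupied. Whether these sites are those of the textbook control region was not tested, so the sums cover these 3 sites and not that region. The 129/Ola sequence was not used here, and a difference from the reference was not tested.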

How the results depend on the processing

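Alternatives gave 381 values for 65 results, 340 of them from alternatives planned beforehand. Of the values of results that answer a comparison, 49 of 69 kept their direction and side of the threshold, or moved by less than their spread, while 14 moved further, 2 lost the threshold and 4 reversed. Those chosen after seeing the data were the strongest 10000 for the rank correlation, windows centred on genes, the whole peak and its variants for the motif, cleaned flanks, motifs above threshold, and neighbours under 20 kb apart. For each change below whose construction does not show it, the cause was not tested. No paired analysis was possible because the series has a single group.

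The replicate overlap of 85.8% was 79.1% for the top 10000, 43.1% for the top 100000, 87.4% with any overlapping base, 79.3% within 50 bp and 87.4% within 250 bp. The rank correlation of 0.891 was 0.931 for all matched peaks and 0.565 for the strongest 10000. The SD of the log2 ratio, 0.42 in the main setting, was 0.508 and 0.279 in that order. The share of optimal peaks in the conservative set was 91.3% with summits within 50 bp and with 50% reciprocal overlap. Overlap in mm9 was 88.9% for the strongest 50% of each list. The X ratio of 0.627 was 0.755 for mm9 peaks with a motif, where the build and scale change as well and all mm9 peaks gave 0.721, and 0.346 for peaks per Mb. Motif score against fold enrichment, at -0.0325, was 0.130 with the best motif of the whole peak and 0.0673 to 0.0830 leaving out each replicate. Convergent pairs were 25.5% at 20 to 500 kb and 24.7 to 24.8% leaving out each replicate, and divergent pairs 26.7% under 20 kb. The B2-related share of 18.2% was 12.3% with 2 mismatches and 29.4% with 4, and the ratio to positions 5 kb away fell from 4.27 to 2.55 with 4. The motif share of 47.2% was 30.3% within 25 bp, 15.3% for the whole peak and 31.0% for the whole peak with cleaned flanks.

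Loci past the test went from 2 to 1 with 100 kb flanks and to 1 with windows centred on protein-coding genes. Loci that did not pass changed sides of a ratio of 1 as follows. With 0 kb flanks H19/Igf2 was at 0.536, Nanog, Sox2 and Myc at 0, Igf2r/Airn at 0.543, Grb10 at 1.37 and Rasgrf1 at 1.27. With 100 kb flanks Myc was at 0.551, Peg3 at 0.957 and Rasgrf1 at 1.71. With windows centred on protein-coding genes H19/Igf2 was at 0.920, HoxC at 0.467, Myc at 0.457, Mycn at 0.655, Dlk1-Meg3 at 0.845, Igf2r/Airn at 0.879 and Peg3 at 0.745. Leaving out each replicate gave 0.793 to 1.05 for HoxC, 0.898 to 1.12 for Rasgrf1, 0.980 to 1.31 for Gnas and 1.02 to 1.02 for Epha4/Pax3.

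Gene lists that did not pass changed sides of their background as follows. With 2500 bp windows pluripotency was at 20%, feeder fibroblast at 25%, lineage factors at 23.9%, architectural at 19.2% and Hox at 17.9%. With 5000 bp windows pluripotency was at 40%, feeder fibroblast at 35%, lineage factors at 39.1% and imprinted at 36.4%. With the strongest 10000 peaks feeder fibroblast was at 5% and architectural at 0%. Against lists matched on CpG ratio, Hox at 12.8% and serpins at 8.16% changed sides. Leaving out each replicate gave 5 to 10% for pluripotency and 10 to 10% for feeder fibroblast.

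The optimal set and the pooled mm10 list were not run for results moved to mm9, and repeat-masked summits were not computed. The unknown depth limits every statement about weak or missing peaks.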

Other observations

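Promoters of intermediate CpG content carried CTCF peaks most often. Of genes ordered by the observed over expected CpG ratio around the transcription start, 3.75% of the lowest quartile had a promoter peak, 11.2% of the second, 15.7% of the third and 10.6% of the highest. Promoter peaks were slightly weaker than others, with a median fold enrichment of 11.2 against 12.1 in intergenic sequence and 12.7 in exons, and 12.9 against 13.99 in replicate 1 and 13.2 against 14 in replicate 2 for promoter against intergenic peaks. Across protein-coding genes these values are descriptions with no test.

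A stricter definition than that of the report was used for peaks without a clear CTCF motif, namely no motif of at least 19.8 bits anywhere in the peak, so many of them hold a motif by the threshold of 14.9 bits. In these 26786 pooled mm9 peaks, 0 of 11 consensus sequences of other factors were more frequent than in flanking windows after Benjamini-Hochberg adjustment. The lowest adjusted p among those in excess was that of the ETS sequence CCGGAAGTG, at 0.183% against 0.108% (Fisher's exact test, adjusted p = 0.135, unadjusted 0.0307). The ESRRB sequence TCAAGGTCA was less frequent in these peaks than in flanks, 0.590% against 0.784% (Fisher's exact test, adjusted p = 0.0475). Its reversed control ACTGGAACT showed a similar ratio, 0.758 against 0.752 (0.362% against 0.478%, Fisher's exact test, unadjusted p = 0.0448, adjusted 0.179), which does not set ESRRB apart from its control in these peaks. In peaks with a motif of at least 19.8 bits, ESRRB was at 0.478% against 0.979% (Fisher's exact test, adjusted p = 3.77e-05). There its control was at 0.629% against 0.549% (Fisher's exact test, adjusted p = 0.861). A reversed control sequence of CREB, ACTGCAGT, was in excess at 1.36% against 0.679% (Fisher's exact test, adjusted p = 1.28e-13). In peaks with a motif of at least 19.8 bits it was at 1.23% against 0.597% (Fisher's exact test, adjusted p = 3.77e-06). Whether this sequence is neutral at CTCF sites was not tested, so its excess sets no background level for the other sequences.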
